A study of Mus musculus with 4 samples.

How the data were processed

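Gene expression was profiled by sequencing of total RNA from dissected dorsal striatum and nucleus accumbens of mice aged over 20 months. The animals carried a transgene in which the Drd1 promoter drives a fusion of EGFP with the ribosomal protein Rpl10a, a construct made for translating ribosome affinity purification. All 4 libraries were of the input kind per the labels, taken here as RNA that was not pulled down with tagged ribosomes. The labels do not say how the input was prepared. Groups were taken from the tissue named in the labels, with 2 libraries per region.

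The authors deposited raw counts of reads per gene symbol, 1 file per library. Reads were aligned with STAR 2.0.0e and counted with HTSeq on the mouse build mm10, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. Some gene rows carry GenBank-type names such as AK140265 and have no gene symbol. The ribosomal protein genes have many near-identical pseudogenes, and their counts are uncertain for that reason.

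The files held 32531 gene rows. The rows for reads in no feature, ambiguous reads and reads with several alignments named no gene and stayed out of library sizes and tests. Reads in no feature made up 35.4% and 29.6% of all counted rows in dorsal striatum replicates 1 and 2, and 29.8% and 27.5% in accumbens replicates 1 and 2. Ambiguous reads made up 6.06% to 9.46%, and reads with several alignments 6.98% to 10.2%. A row named unknown held 0 counts in every library.

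Depth per library, as counts assigned to genes, was 8991788 and 11849134 in dorsal striatum and 8606099 and 8478403 in accumbens. Reads carry no molecular identifiers, so the floor of 3 counts covers counting error only.

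Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest with defaults) in R 4.3.3, with region as the only term. The filter filterByExpr left 14493 genes. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a single gene comes from this edgeR test unless another tool is named. Fold changes are accumbens over dorsal striatum on the log2 scale, and the standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts relative to library size), given as mean ± SD over the 2 libraries of a region. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

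Before the data were examined, 38 gene lists were fixed from textbook knowledge of striatal neurons, other brain cell types, neighbouring regions, signalling families and sample quality. The 29 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over these lists. Each list also has its count of genes past the threshold over all tested genes, and its count adjusted over the list alone.

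The rule for named genes was also fixed before the data were examined. It takes Drd1, then the 10 genes with the largest fold change in each direction among those past the threshold, with non-overlapping groups and a mean log2 CPM of at least 1, passing over names that start with Gm and digits or with LOC, or that end in Rik (GenBank-type names were not passed over). From each list it takes up to 4 members past the threshold, or, where none passed, the 2 members with the highest mean CPM. Values of some genes that this rule takes are not reported here. The rule assigned ribosomal protein genes to a share of counts only. Tests on those genes were therefore an addition made after the data were seen, and the list was changed once its first values were known, with genes both taken out and brought in.

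Alternatives covered the scaling (DESeq2 size factors, upper quartile, library size only), the low-count filter, the tool (DESeq2 1.42.0, limma-voom), a robust fit, a replicate block, a minimum fold of 1.5, each library left out in turn and the 50 most abundant genes left out. For the lists they covered an estimated correlation and fry. Chosen after seeing the data were the edgeR fit with legacy=FALSE, voom with a weight per group, and offsets for transcript length and for GC content. Transcript lengths and GC content were those of the longest protein-coding transcript per symbol in the GENCODE annotation of GRCm38. Its chromosomes are those of mm10, and gene coordinates came from it too. A length was found for 85.7% of the tested genes and for 93.5% of those past the threshold.

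The procedure was tested on simulated data for the comparison of accumbens with dorsal striatum, with 200 changed genes. Over 14006 simulated genes it recovered 50% of 2-fold and 87% of 4-fold changes, and 8 of its 145 calls were false. The simulated spread was the same in both regions, unlike that of the real libraries. These figures thus describe the simulated data and cannot be carried over to the real comparison. A shifted list was called with the preset correlation and was not called with the estimated one. Its genes were simulated without correlation, while estimated correlations of the real lists ran from −0.20 to 0.77. The simulation thus cannot decide which setting suits the real lists.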

Results

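Gene expression was compared between the nucleus accumbens and the dorsal striatum of aged mice, 2 parts of the striatum that contain the same main classes of spiny projection neuron (SPN). Each region had 2 libraries of input RNA, with 8478403 to 11849134 counts assigned to genes. The dorsal striatum libraries detected 19519 and 19532 genes with at least 1 count, and the accumbens libraries 16915 and 17417. After thinning to 8478403 counts these numbers were 19433 and 19096 against 16903 and 17417. The ribosomal RNA precursor row Rn45s took 2.03% and 3.34% of counts in dorsal striatum and 5.61% and 5.94% in accumbens. The row AK140265 took 6.92% and 4.38% against 9.29% and 10.3%.

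The question was which genes differ in level between these regions in old animals of the Drd1 reporter line. The accumbens had higher levels of the neuropeptide genes Cck and Cartpt, of the dopamine receptor gene Drd3, and of the imprinted genes Nnat and Dlk1. The dorsal striatum had higher levels of the cannabinoid receptor gene Cnr1, of Coch, which encodes the secreted protein cochlin, and of Clspn, which encodes the checkpoint adaptor claspin. Of 14493 genes tested, 186 passed the threshold, 144 of them higher in accumbens and 42 higher in dorsal striatum. Fitted fold changes were above 2 for 97 and 24 of these genes, and a test against a minimum fold of 1.5 (glmTreat in edgeR) left 0 genes, with 889 at an unadjusted p under 0.05. All 186 had non-overlapping groups, as did 51.2% of all tested genes, where chance gives 33.3%.

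The split between directions depended on the scaling. With TMM 77.4% of the calls were higher in accumbens, with upper-quartile scaling 67.4%, and with library size alone 29.5% (72 higher and 172 lower). Scaling by library size moved the median log2 fold change of all genes from 0.02 to −0.15, and all 186 genes kept their sign under it. Fold changes also varied with transcript length, mainly among the shortest genes, and with GC content. The shortest decile had a median of 0.27 (23 calls higher and 0 lower) and the longest 0.02 (22 and 10). Length decile 2 had 0.09, and all longer deciles lay between −0.03 and 0.02. By GC content the lowest decile had −0.05 (9 and 2) and the highest 0.31 (13 and 4), while decile 9 had 0.22 (27 and 0). With the length offset 72.6% of calls were higher, 8 of them in the shortest decile, and with the GC offset 67.0%. Leaving out a library moved the count of 186 to 109 without dorsal striatum replicate 1, to 2789 without accumbens replicate 1 and to 4464 without accumbens replicate 2, where the lone accumbens library was taken to vary like the dorsal striatum pair. List counts moved with it, with the low-count filter applied anew, and are given below where leaving out a library changed them by over 1.5 times or added calls in the other direction.

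**Figure D1:**
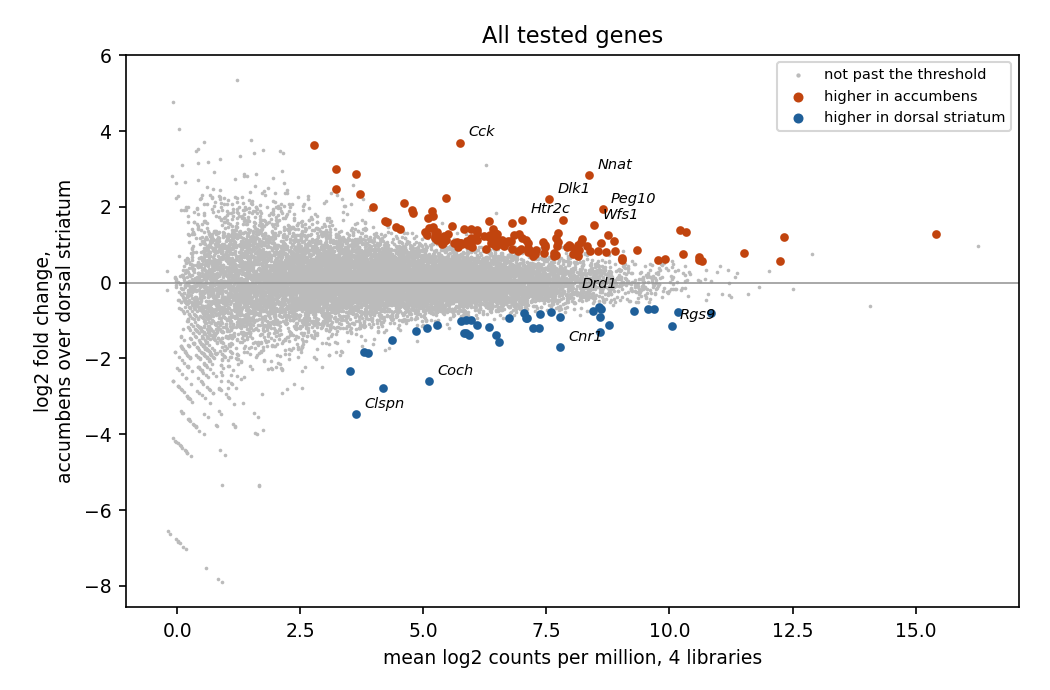
Log2 fold change of accumbens over dorsal striatum (vertical axis) against the mean log2 CPM of the 4 libraries (horizontal axis) for the 14493 tested genes, with TMM scaling. Coloured points are the 144 genes past the threshold that were higher in accumbens and the 42 that were higher in dorsal striatum.

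Drd1, the dopamine receptor gene whose promoter drives the transgene (chromosome 13, 54051183 to 54055705, minus strand), was at 239 ± 26.8 CPM in accumbens and 293 ± 10.2 CPM in dorsal striatum (SD, n = 2 each). Its log2 fold change of −0.29 (SE 0.13) did not pass the threshold (edgeR adjusted p = 0.273).

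Among the genes with the largest differences, Cck, which encodes the neuropeptide cholecystokinin (chromosome 9, 121489824 to 121495694), was 13.0-fold higher in accumbens, at 99.8 ± 61.2 against 7.85 ± 5.69 CPM. The log2 fold change was 3.70 (SE 0.57, edgeR adjusted p = 0.0348). The gene of its receptor, Cckbr, was 5.09-fold higher. Cartpt, which encodes the CART peptide (chromosome 13, 99898489 to 99901091), stood at 21.7 ± 0.405 against 2.95 ± 0.901 CPM, a log2 fold change of 2.86 (SE 0.37). Drd3 (chromosome 16, 43754026 to 43822932) stood at 15.7 ± 2.57 against 2.80 ± 0.993 CPM, a log2 fold change of 2.47 (SE 0.42). The remaining genes of this group were Glt8d2, a glycosyltransferase gene (3.64), the retinol transporter gene Stra6 (3.01), Nnat (2.84), the heparan sulfate sulfatase gene Sulf1 (2.24), Dlk1 (2.21) and the sterol-binding protein gene Stard5 (2.12), given as log2 fold changes.

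The accumbens libraries differed from each other in several of these genes. Nnat was at 863 and 298 CPM in accumbens replicates 1 and 2, Cck at 143 and 56.5 CPM, Glt8d2 at 19.2 and 6.13 CPM, and Stra6 at 23.5 and 9.63 CPM. In the same libraries Slc17a7, the vesicular glutamate transporter gene of cortical excitatory neurons, was at 198 and 79.4 CPM. Without accumbens replicate 1 the log2 fold changes were 2.89 for Cck, 2.60 for Glt8d2, 2.22 for Stra6 and 1.87 for Nnat. Cck gave 4.68 and 3.06 without dorsal striatum replicates 1 and 2, and Glt8d2 gave 4.25 without accumbens replicate 2.

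Among the genes that the naming rule took, the largest difference in the other direction was that of Clspn (chromosome 4, 126556935 to 126593903). It was 11.1-fold higher in dorsal striatum at 22.2 ± 1.02 against 2.00 ± 1.24 CPM (log2 fold change −3.47, SE 0.46, edgeR adjusted p = 0.0262). Coch (chromosome 12, 51593341 to 51605771) stood at 58.9 ± 8.69 against 9.69 ± 4.86 CPM, and Cnr1 (chromosome 4, 33924593 to 33948831) at 332 ± 21.1 against 103 ± 12.7 CPM. Their log2 fold changes were −2.60 (SE 0.34) and −1.69 (SE 0.14). Ddit4l (−2.77), Sec14l3 (−2.33), the unnamed transcript row AK141353 (−1.87), Fam84b (−1.82), the activin receptor gene Acvr1c (−1.56), Pld5 (−1.50) and the cyclin gene Ccnd2 (−1.39) completed the group. Without accumbens replicate 2 the values were −4.30 for Clspn and −3.45 for Ddit4l, and without accumbens replicate 1 Coch was at −3.23.

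Of these 20 genes, 8 lost the threshold when a dorsal striatum library was left out. Without replicate 1 the edgeR adjusted p was 0.0635 for Stra6, 0.218 for Drd3, 0.0803 for Sec14l3, 0.407 for AK141353, 0.339 for Fam84b and 0.0899 for Pld5. Without replicate 2 it was 0.0683 for Glt8d2, 0.0636 for Drd3, 0.143 for Cckbr, 0.182 for Sec14l3, 0.0875 for AK141353, 0.169 for Fam84b and 0.446 for Pld5. With DESeq2 size factors Glt8d2, Stra6, Fam84b and Pld5 missed the threshold narrowly (0.0525 to 0.0529), as did Fam84b and Pld5 without the 50 most abundant genes (0.0503 and 0.052), and with limma-voom Glt8d2 and Stra6 were at 0.104 and 0.0618.

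**Figure D2:**
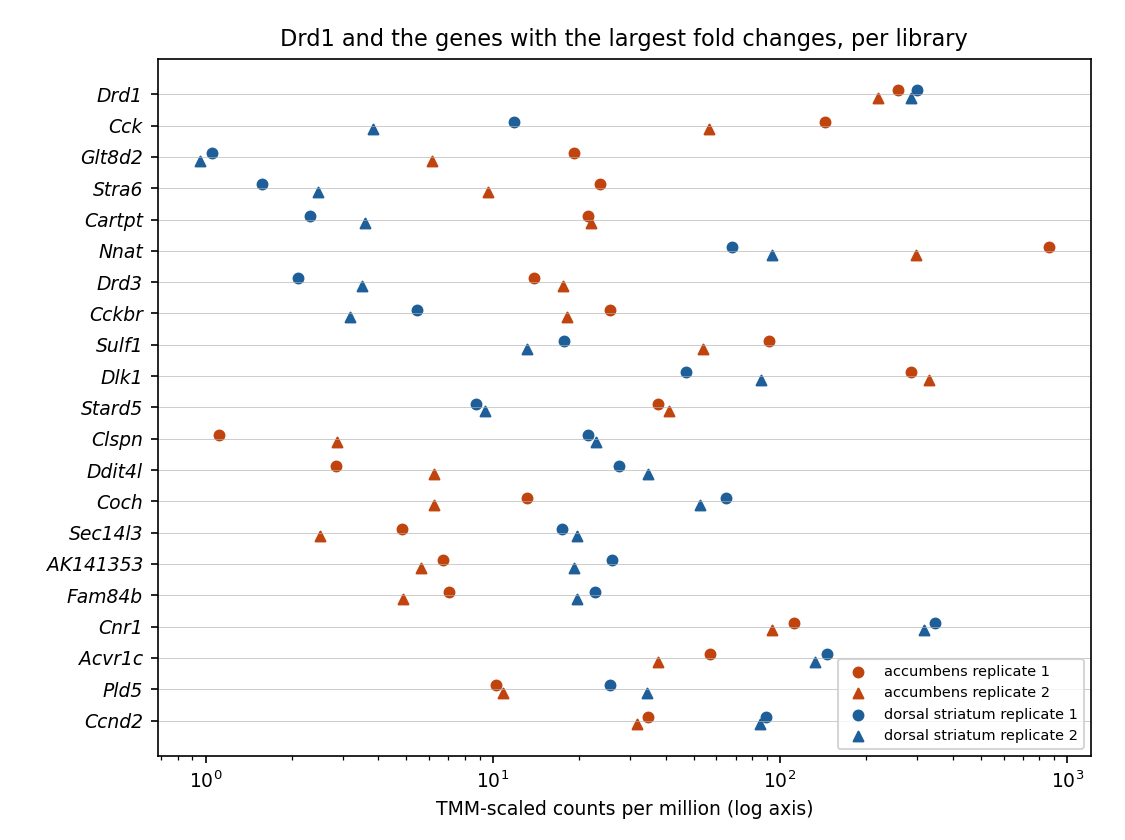
TMM-scaled CPM on a log axis (horizontal) for Drd1 and the 20 genes that the naming rule took for their fold changes (vertical). Each point is 1 library, coloured by region and shaped by replicate number. The regions do not overlap for these 20 genes, and the accumbens points of Nnat lie at 863 and 298.

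Of 10 tested genes known as accumbens markers, 6 passed the threshold (8 when adjusted over the list alone), all higher in accumbens, and the median log2 fold change was 1.82. Wfs1, which encodes wolframin, stood at 522 ± 68.9 against 182 ± 25.1 CPM (log2 fold change 1.52, SE 0.15), and Dlk1 at 308 ± 29.9 against 66.5 ± 27.3 CPM. Camera gave an adjusted p of 6.26e-07, with an adjusted p = 0.865 with an estimated correlation. Of the 4 markers of dorsal striatum, Cnr1 and Coch passed and were higher in dorsal striatum (4 when adjusted over the list alone), with a median of −1.31 and too few members for a set test. Without accumbens replicate 1 or 2, 9 accumbens markers were higher in accumbens and 4 markers of dorsal striatum were higher in dorsal striatum, and the latter count was 3 without dorsal striatum replicate 1.

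Several neuropeptide genes were higher in accumbens. Cck, Cartpt, Sst and Pdyn passed among 12 tested members (5 when adjusted over the list alone), and 11 had a positive fold change. Sst, the somatostatin gene of a class of interneuron, stood at 168 ± 35.9 against 55.9 ± 3.49 CPM, and Pdyn, the prodynorphin gene, at 175 ± 18.2 against 71.4 ± 8.95 CPM. The median was 1.10 and camera gave an adjusted p of 8.71e-05, with an adjusted p = 0.865 with an estimated correlation. Without accumbens replicate 1, 7 neuropeptide genes were higher, and without accumbens replicate 2, 8 were higher and 1 lower. Opioid receptor genes followed with 2 of 4 members higher in accumbens (2 when adjusted over the list alone). These were Oprk1, the kappa receptor gene (1.29, SE 0.20), and Oprm1, the mu receptor gene (1.47, SE 0.26). Without dorsal striatum replicate 1 the edgeR adjusted p of Oprk1 was 0.135 and that of Oprm1 0.192. Oprm1 also missed the threshold with DESeq2 size factors and with library size alone (0.0525 and 0.0519). Of opioid receptor genes 0 passed without dorsal striatum replicate 1 and 3 were higher without accumbens replicate 1, and 2 were higher and 1 lower without accumbens replicate 2.

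Among serotonin receptor genes Htr2c was higher in accumbens, at 195 ± 22.8 against 61.5 ± 3.49 CPM (log2 fold change 1.66, SE 0.15). It was the single member of 11 to pass (3 when adjusted over the list alone), and the median was 0.98. Camera called the list with an adjusted p of 0.0305, against an adjusted p = 0.865 with an estimated correlation, 0.280 without accumbens replicate 1 and 0.0503 without accumbens replicate 2. Without accumbens replicates 1 and 2, 4 and 5 members were higher, and 1 was lower in each case. No immediate early gene passed among 13 (3 when adjusted over the list alone), although 12 had a positive fold change and the median was 0.73. Egr1 was at 483 ± 161 against 416 ± 34.8 CPM and Nr4a1 at 103 ± 35.9 against 61.9 ± 15.1 CPM. Camera called this list with an adjusted p of 0.0204, against an adjusted p = 0.869 with an estimated correlation, 0.0805 without dorsal striatum replicate 1 and 0.452 without accumbens replicate 1. Without accumbens replicate 1, 2 immediate early genes were higher and 1 lower, and without accumbens replicate 2, 9 were higher.

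Genes of SPN identity shared by all SPNs differed in a few members. Rgs9, a regulator of G protein signalling, was at 661 ± 2.79 CPM in accumbens and 1452 ± 195 CPM in dorsal striatum (log2 fold change −1.13, SE 0.13), and Rasd2 at 223 ± 38.9 against 551 ± 54.2 CPM (−1.30, SE 0.15). These were the 2 of 16 members to pass (6 lower and 1 higher when adjusted over the list alone), and camera gave an adjusted p of 0.108. Without accumbens replicate 1, 6 were lower, and without accumbens replicate 2, 3 were higher and 4 lower. Of 16 genes of dopamine and cAMP signalling, Rgs9 and Rgs4 (−1.12) were lower in accumbens and Drd3 was higher (4 lower and 1 higher when adjusted over the list alone), with an adjusted p of 0.440 in camera. In that list 0 were higher and 2 lower without dorsal striatum replicate 1 or 2, 1 higher and 4 lower without accumbens replicate 1, and 4 higher and 3 lower without accumbens replicate 2. Of 9 direct pathway genes only Pdyn passed (1 when adjusted over the list alone, camera adjusted p 0.400), with 1 higher and 1 lower without accumbens replicate 1 and 4 higher without accumbens replicate 2. Of 8 indirect pathway genes none passed over all genes or over the list alone (camera adjusted p 0.252), with Penk at 928 ± 223 against 665 ± 113 CPM and Drd2 at 116 ± 15.7 against 128 ± 3.08 CPM, and 5 were higher without accumbens replicate 2.

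Of 9 striosome markers Oprm1 passed (5 when adjusted over the list alone), and camera gave an adjusted p of 0.118. The count was 0 without dorsal striatum replicate 1, 1 higher and 1 lower without accumbens replicate 1, and 7 higher and 1 lower without accumbens replicate 2. Of 6 matrix markers none passed (1 lower when adjusted over the list alone, camera 0.729), with Sv2b at 380 ± 130 against 316 ± 8.35 CPM and Epha4 at 210 ± 33.7 against 198 ± 1.42 CPM, and without accumbens replicate 1 or 2, 1 was higher and 1 lower. Cholinergic interneuron genes had no member past the threshold among 7 in either adjustment (camera 0.208), with Slc5a7 at 43.1 ± 9.52 against 47.2 ± 0.186 CPM and Tacr1 at 25.4 ± 6.50 against 32.5 ± 4.20 CPM, and 1 was lower without accumbens replicate 2. Sst was the single GABA interneuron gene of 9 to pass (2 when adjusted over the list alone, camera 0.526), with 5 higher without accumbens replicate 1 and 2 higher and 3 lower without accumbens replicate 2.

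Of the imprinted genes, 4 genes were higher in accumbens among 22 tested (4 higher and 2 lower when adjusted over the list alone). Peg10 stood at 633 ± 14.1 against 164 ± 50.2 CPM (log2 fold change 1.95, SE 0.20) and Mest at 179 ± 17.2 against 78.7 ± 10.02 CPM (1.18, SE 0.16), beside Dlk1 and Nnat. The list's median was 0.11 and camera gave an adjusted p of 0.400. Without dorsal striatum replicate 1, 4 were higher and 1 lower, and without accumbens replicates 1 and 2, 6 were higher in each case and 2 and 5 lower.

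Markers of neighbouring tissue were measured in the same libraries. Cortical glutamatergic neuron genes had no member past the threshold among 11 in either adjustment, with a median of 1.09 and a camera adjusted p of 0.0577. Without dorsal striatum replicates 1 and 2, 4 and 1 were higher, without accumbens replicate 1, 3 were higher, and without accumbens replicate 2, 6 were higher and 1 lower. Slc17a7 stood at 139 ± 83.8 against 16.5 ± 22.3 CPM and Rorb at 70.5 ± 23.8 against 57.2 ± 10.2 CPM. Among 5 septum markers the heparan sulfate enzyme gene Ndst4 was higher in accumbens (1.47, SE 0.27; 1 when adjusted over the list alone), with a camera adjusted p of 0.903. Its edgeR adjusted p was 0.331 and 0.152 without dorsal striatum replicates 1 and 2, and between 0.0508 and 0.0554 with each other scaling, the length offset or the 50 most abundant genes left out. Without accumbens replicate 2, 1 septum marker was higher and 2 were lower. Of 3 markers of the islands of Calleja, Drd3 was higher (1 higher and 1 lower when adjusted over the list alone), with 0 without either dorsal striatum replicate, 1 higher and 1 lower without accumbens replicate 1, and 1 higher and 2 lower without accumbens replicate 2. Of 3 tested genes of hypothalamus or pallidum none passed in either adjustment, with Slc17a6 at 11.7 ± 11.5 against 18.8 ± 5.06 CPM and Nkx2-1 at 6.04 ± 0.831 against 6.35 ± 0.0805 CPM, and 2 were lower without accumbens replicate 2.

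Glial, vascular and other non-neuronal markers gave 1 call, that of the astrocyte gap junction gene Gja1 (1.01, SE 0.19; 2 of 12 higher when adjusted over the list alone, camera 0.252). Its edgeR adjusted p was 0.351 and 0.234 without dorsal striatum replicates 1 and 2, and it missed the threshold under each other scaling (0.0529 to 0.0612) and without the 50 most abundant genes (0.0536). Without accumbens replicates 1 and 2, 3 and 4 astrocyte genes were higher, and without dorsal striatum replicate 2 none passed. Among 13 oligodendrocyte genes (1 higher and 1 lower when adjusted over the list alone, camera 0.464), Mbp was at 726 ± 39.7 against 484 ± 91.3 CPM. Of these, 2 were higher without dorsal striatum replicate 1, 1 was lower without dorsal striatum replicate 2, 4 were higher and 1 lower without accumbens replicate 1, and 1 was higher and 4 lower without accumbens replicate 2. Among 7 genes of oligodendrocyte precursors (camera 0.154), Pdgfra was at 47.3 ± 0.485 against 41.2 ± 1.34 CPM and Olig1 at 42.2 ± 15.7 against 34.9 ± 4.02 CPM. Among 12 microglial genes (camera 0.108), Csf1r was at 33.4 ± 0.400 against 22.6 ± 2.16 CPM and C1qb at 16.8 ± 6.40 against 15.5 ± 5.52 CPM. Among 10 vascular genes (camera 0.734), Flt1 was at 18.6 ± 16.2 against 6.27 ± 4.81 CPM and Rgs5 at 7.83 ± 1.71 against 8.66 ± 3.35 CPM. The last 3 lists had 0 members past the threshold when adjusted over the list alone. Without accumbens replicate 1, 3 precursor genes were higher and 1 lower, and without accumbens replicate 2, 4 microglial and 4 vascular genes were higher and 1 of each lower.

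A further 5 lists had no gene past the threshold over all genes and too few tested members for a set test. They were 3 ependymal genes (2 lower when adjusted over the list alone), 4 choroid plexus genes (1 higher), 2 meningeal genes, 2 blood genes and 4 sex-linked genes (2 lower). Foxj1, a gene of ciliated cells, was at 1.93 ± 0.628 against 7.13 ± 0.616 CPM, and Rsph1 at 7.14 ± 3.56 against 6.54 ± 1.23 CPM. Clic6 was at 20.4 ± 5.94 against 18.3 ± 3.69 CPM and Prlr at 9.74 ± 10.6 against 13.8 ± 6.03 CPM. Igf2 was at 9.20 ± 2.76 against 6.77 ± 0.675 CPM, Col1a2 at 0.936 ± 0.974 against 1.06 ± 0.307 CPM, Alas2 at 5.98 ± 2.15 against 6.85 ± 1.46 CPM and Hbb-bs at 1.93 ± 0.427 against 3.30 ± 1.99 CPM. The Y-linked genes Ddx3y and Kdm5d were at 46.1 ± 13.9 against 72.5 ± 7.16 CPM and 38.4 ± 3.80 against 70.2 ± 2.10 CPM. Of 8 genes of the neurogenic niche none passed in either adjustment (camera 0.154), with Dcx at 75.9 ± 13.0 against 52.7 ± 4.56 CPM and Sox11 at 39.8 ± 1.24 against 29.3 ± 2.87 CPM. Without accumbens replicates 1 and 2, ependymal genes had 2 lower in each case, sex-linked genes 2 and 3 lower, choroid plexus genes 1 higher in each case with 1 lower in the second, and niche genes 1 and 2 higher.

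The remaining receptor and channel families gave 1 call. Kcnc1, a voltage-gated potassium channel gene, was higher in accumbens at 194 ± 3.72 against 114 ± 2.94 CPM (log2 fold change 0.77, SE 0.13), 1 of 24 channel genes (2 higher and 2 lower when adjusted over the list alone, camera 0.997). Its edgeR adjusted p was 0.217 and 0.128 without dorsal striatum replicates 1 and 2, 0.0597 with library size alone and 0.0687 with the GC offset. Of channel genes 0 passed without either dorsal striatum replicate, 2 were higher and 6 lower without accumbens replicate 1, and 6 were higher and 3 lower without accumbens replicate 2. None of 22 glutamate receptor genes passed (3 higher and 1 lower when adjusted over the list alone, camera 0.137), with Gria2 at 1063 ± 112 against 1187 ± 10.8 CPM and Gria1 at 490 ± 13.2 against 520.0 ± 32.3 CPM. None of 13 GABA-A receptor genes passed (6 higher when adjusted over the list alone, camera 0.153), with Gabrb2 at 327 ± 13.1 against 343 ± 16.4 CPM. None of 5 steroid receptor genes passed in either adjustment (camera 0.903), with Nr3c1 at 81.5 ± 15.4 against 104 ± 10.7 CPM and Nr3c2 at 62.6 ± 11.1 against 49.8 ± 0.447 CPM. Without accumbens replicates 1 and 2, 3 and 6 glutamate receptor genes were higher and 1 was lower in each case, 5 GABA-A receptor genes were higher and 1 was lower in each case, and 2 steroid receptor genes were higher and 3 lower in the second case.

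Lists for age, stress and metabolism gave 1 call. Ndufa4, a mitochondrial respiratory chain gene, was higher in accumbens at 59.0 ± 5.51 against 27.2 ± 0.738 CPM (log2 fold change 1.12, SE 0.19), 1 of 20 members (2 higher when adjusted over the list alone, camera 0.154). Its edgeR adjusted p was 0.217 and 0.149 without dorsal striatum replicates 1 and 2, 0.0519 with library size alone and 0.109 with the length offset. None of 9 aged glia genes passed in either adjustment (camera 0.751), with Apoe at 176 ± 24.4 against 133 ± 29.2 CPM and Gfap at 26.1 ± 7.12 against 38.5 ± 33.4 CPM. None of 6 interferon genes passed in either adjustment (camera 0.440), with Ifi27 at 9.70 ± 0.993 against 7.26 ± 0.129 CPM. None of 5 heat shock genes passed in either adjustment (camera 0.891), with Hspa8 at 1057 ± 27.2 against 1083 ± 2.09 CPM and Hsp90aa1 at 635 ± 95.5 against 722 ± 13.1 CPM. Without accumbens replicates 1 and 2, 4 and 3 respiratory chain genes were higher, with 2 lower in the second case, and without either dorsal striatum replicate 0 passed. For interferon genes 2 were lower without either accumbens replicate, and for aged glia genes 2 were lower without replicate 1 and 1 was higher and 1 lower without replicate 2. Ribosomal protein genes took 0.295% and 0.334% of counts in dorsal striatum and 0.368% and 0.394% in accumbens.

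The lists' median, mean and camera test differed in sign in 6 cases. The median and mean were −0.35 and −0.33 for septum with an upward test, −0.01 and 0.35 for GABA interneurons (upward), −0.04 and 0.02 for voltage-gated channels (upward), 0.04 and −0.27 for steroid receptors (downward), 0.11 and −0.0011 for aged glia (upward), and −0.03 and 0.12 for heat shock (upward). The islands of Calleja, with no set test, had a median of −0.16 and a mean of 0.20. Of the 29 lists tested, 4 passed with the preset correlation and 0 with an estimated one, where 0 lists had an unadjusted p under 0.05.

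**Figure D3:**
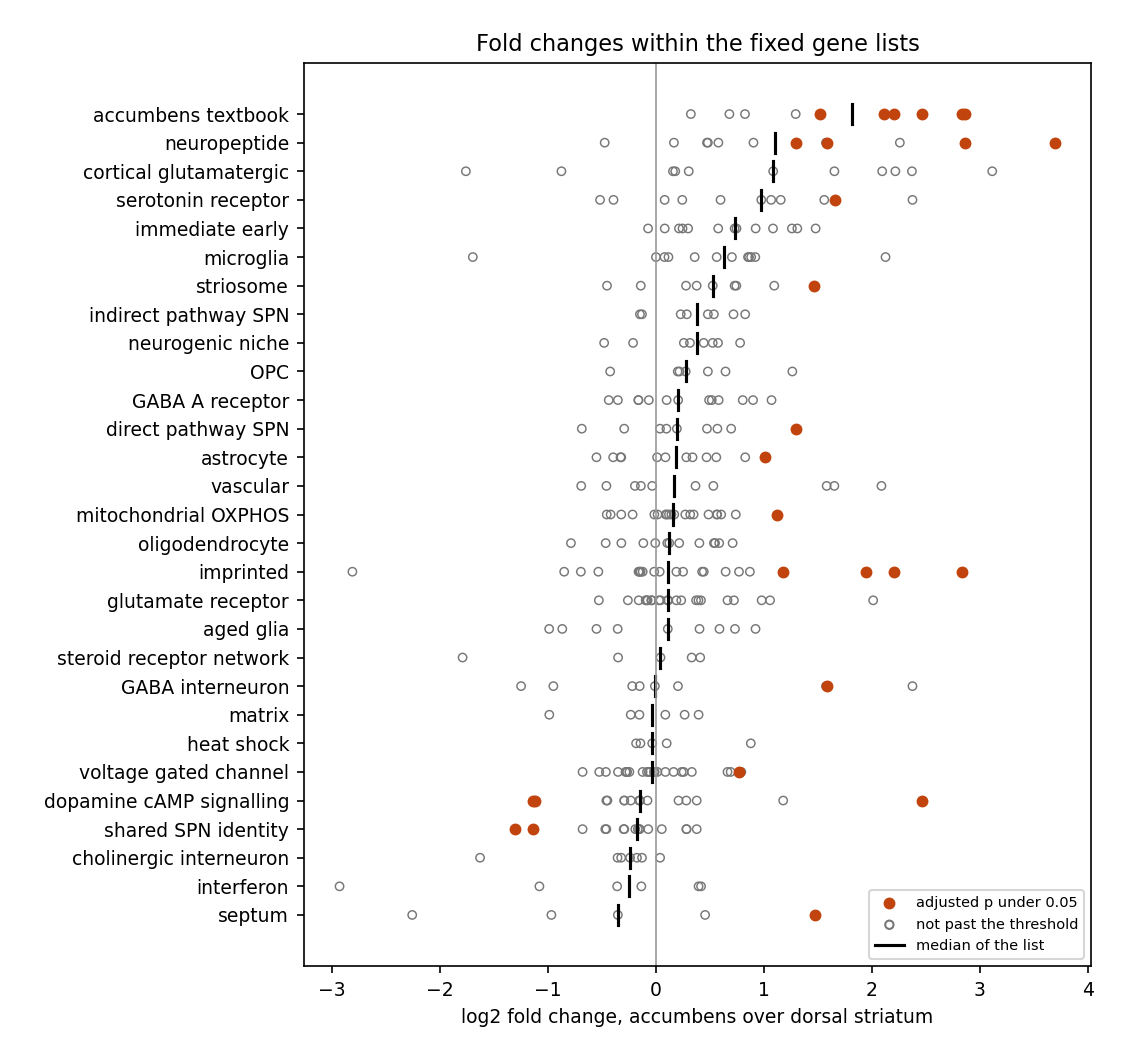
Log2 fold change of accumbens over dorsal striatum (horizontal axis) of each tested member of the 29 lists with at least 5 tested members (vertical axis, ordered by median). Filled points passed the threshold, open points did not, and bars are list medians, from 1.82 for accumbens markers to −0.35 for septum markers.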

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

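Reads that fell in no annotated feature were outside the comparison in every library and were flagged as data left unanalysed. They made up 35.39% and 29.57% of all counted rows in dorsal striatum replicates 1 and 2, and 29.78% and 27.46% in accumbens replicates 1 and 2. No explanation was tested for these shares. Groups of 2 libraries are too small for a test of single outlying libraries.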

How the results depend on the processing

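The edgeR fit with legacy=FALSE, voom with a weight per group and the length and GC offsets were chosen after seeing the data. The planned fit with legacy=TRUE is the default of the edgeR version used and coincides with the reported one. Against 186 genes past the threshold (144 higher and 42 lower in accumbens), the count was 1203 (768 and 435) with no low-count filter, 918 (610 and 308) with the DESeq2 Wald test, 431 (310 and 121) with limma-voom, 371 (267 and 104) with legacy=FALSE and 656 (497 and 159) with a weight per group. With library size alone it was 244 (72 and 172). With the GC offset 132 were higher and 65 lower (67.0% higher). A minimum fold of 1.5 (glmTreat in edgeR) gave 0 (0 and 0), with 889 genes at an unadjusted p under 0.05. Leaving out 1 library gave 109 to 4464 genes, 81 to 2386 higher and 28 to 2078 lower in accumbens. With an accumbens library left out, the lone library was assumed to vary like the dorsal striatum pair. The accumbens pair spread more (overdispersion 12.8 against 2.67 at 20 to 50 mean counts), and the count was highest where its spread did not enter. The cause of the other shifts was not tested.

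All 186 genes kept their sign under each alternative that gave them a value. Since their groups did not overlap, leaving out a library could hardly reverse a sign, for these or for the named genes below. For the 36 named genes, 643 values under alternatives other than the minimum fold were followed: 597 stayed on their side of the threshold, 46 lost it and 0 reversed. Left out were 3 values without an adjusted p in DESeq2 (Glt8d2, Stra6 and Drd3). The minimum fold kept 0 of the 186 calls.

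The number of lists past the threshold, 4 as reported, was 0 with an estimated correlation and 0 with fry's directional test (both in limma, with 0 and 5 lists at an unadjusted p under 0.05), 15 with fry's mixed test, and 2 to 7 with a library left out. Of the 22 lists without a gene past the threshold, 13 and 18 gained at least 1 without accumbens replicates 1 and 2, and 2 and 2 without dorsal striatum replicates 1 and 2.

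The replicate numbers are shared between the regions, but nothing ties them to shared animals. Deviations of same-numbered libraries had a correlation of 0.0124 across 10974 genes. Each region had only a pair of libraries and genes are not independent replicates, so this value cannot decide on shared animals. With the replicate block the count was 843 (551 higher and 292 lower), and 6 lists passed. In the simulation, 2-fold changes were recovered in 50% of cases. The simulated spread was the same in both regions. In the real libraries overdispersion was 12.8 in accumbens against 2.67 in dorsal striatum at 20 to 50 mean counts. The simulated share thus cannot be taken as the recovery in the real comparison, and what depth alone limits was not simulated.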

Other observations

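The tests on ribosomal protein genes and on glutamatergic genes, the test of spread at equal depth, the count of detected genes without the most abundant ones, and the genes named next, were chosen only after the values were seen, while the other tests on the spread between libraries and the test of other splits were set before.

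Several genes past the threshold lay outside the lists. Slit2 (log2 fold change 1.44, SE 0.22), Nrp2 (1.12, SE 0.19), Plxna1 (1.04, SE 0.18) and Islr2 (1.75, SE 0.23), which encode an axon guidance ligand, guidance receptors and a membrane protein, were higher in accumbens. Robo2, the gene of a Slit receptor, was lower (−0.79, SE 0.14). The transcription regulator genes Foxp2 (0.80), Zbtb20 (1.09), Lmo4 (1.41) and Klf5 (1.05) were higher in accumbens, and Onecut2 (−1.39), Zbtb18 (−1.33), Dach1 (−1.28) and Hlf (−0.64) were higher in dorsal striatum. Each of these groups was picked from the results and was not tested as a set.

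Camk4 was at 850.1 ± 65.2 CPM in accumbens and 1446 ± 0.874 CPM in dorsal striatum, and Ppp3ca, which encodes a calcineurin subunit, at 1350 ± 163 against 2350 ± 10.2 CPM. Nrgn (−1.18), Ryr3 (−0.69) and Slc8a3 (−0.97) were also lower in accumbens. Camk2a stood at 1875 ± 72.7 against 1228 ± 17.3 CPM, and the sodium-calcium exchanger gene Slc8a1 at 638 ± 9.51 against 295 ± 73.0 CPM, both higher in accumbens. These genes were likewise picked from the results and not tested as a set.

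Ribosomal protein genes had mostly positive fold changes (68 of 75 tested, 6 past the threshold, median 0.57). The first version of this list gave 73 of 86 positive, 5 past the threshold and a median of 0.51, and the change made after these values were seen took out 15 tested genes (10 of them S6 kinase genes by name, and also Rps3a1) and brought in 4, of which 1 (Rplp1) is past the threshold. Among 10000 random lists matched on transcript length the median of the 75 genes lay at percentile 99.88 (matched median 0.29). With GC content matched it lay at percentile 100 (0.03). The median was thus above what either trend gave for other genes. These lists drew genes independently, so a shift shared by the ribosomal protein genes would also give such percentiles, which do not measure evidence over libraries. Lengths of the longest transcript may exceed those of the transcripts present. The first version, which shares most of its genes, gave the same percentiles. The length offset ended all 6 calls, with Rps27 going from 1.71 to 1.18 and Rplp1 from 1.21 to 0.70 and the list's median from 0.57 to 0.27, as folds shrank by the length trend, so length may carry part of the shift. Regional biology, RNA quality and reads shared with pseudogenes stay open, and Rpl10a (1.01, SE 0.16) is also part of the transgene, whose reads its counts cannot separate.

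Glutamatergic neuron genes varied between libraries, with Slc17a7 counts of 307, 9, 1598 and 635 in dorsal striatum replicates 1 and 2 and accumbens replicates 1 and 2. In the same order, Neurod6 (70, 0, 209 and 59) and Neurod2 (53, 2, 158 and 74) went the same way. Tbr1, with 135, 66, 246 and 241 counts, hardly differed within accumbens, so these genes did not all follow Slc17a7 there. The median log2 ratio of accumbens replicate 1 over 2 was 0.0344 for the 144 genes higher in accumbens (upper quartile 0.221) and 1.32 for Slc17a7. Most of these genes thus did not follow Slc17a7 in this pair. The test favours genes that differ little within a region, and Slc17a7 itself did not pass (edgeR adjusted p = 0.162). A low median was thus favoured in advance, and it cannot decide on 1 shared source. Cck, Glt8d2, Nnat, Stra6 and Sulf1 alone reached at least 0.754, so a differing share of excitatory neurons in the dissections is a candidate source for these 5, untested against a difference within accumbens. In the dorsal striatum pair, where Slc17a7 was at 32.3 and 0.717 CPM, Cck (11.9 and 3.83) and Sulf1 (17.8 and 13.1) went the same way, Glt8d2 hardly differed (1.05 and 0.956), and Nnat (68.0 and 93.9) and Stra6 (1.58 and 2.47) went the other way, which goes against this source for Nnat and, at low levels, for Glt8d2 and Stra6 in that pair. Cck counts per Slc17a7 count were 0.723 and 0.712 in accumbens replicates 1 and 2. In dorsal striatum replicates 1 and 2 they were 0.368 and 5.33, the latter on 9 Slc17a7 counts. The ratio of Cck to Slc17a7 thus held within accumbens but not across the dorsal striatum libraries. Of the 11 tested genes of the cortical glutamatergic list 9 had positive fold changes. Rorb and Lamp5 among them lay between 39.8 and 87.3 CPM in every library.

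The accumbens libraries differed more from each other (r = 0.943 across genes, which are not independent replicates) than the dorsal striatum libraries (0.986). Between regions r ran from 0.931 to 0.954, so the accumbens libraries were no more alike than some pairs across regions. The planned test of depth took squared deviations over the Poisson expectation (overdispersion) at 50 to 200 mean counts. It decided nothing, since both pairs exceeded that expectation (12.93 in accumbens and 3.366 in dorsal striatum). With all libraries thinned to 1 TMM-scaled size, the accumbens overdispersion for the same genes was 4.562 times that of dorsal striatum. The range was 4.381 to 4.813 in 20 thinnings, which argues against depth as the cause. At 20 to 50 mean counts, unthinned, the accumbens overdispersion was 4.787 times that of the dorsal striatum pair. Fewer distinct RNA molecules in the accumbens libraries would give this, so a smaller RNA input may contribute. Variation between animals or dissections cannot be told apart from this, because the test set for it assumed that counting noise was the larger part at such counts, and the squared deviations there were 12.8 and 2.67 times the Poisson expectation in accumbens and dorsal striatum. Without the 50 most abundant genes and thinned to 6140684 counts, 16839 and 17367 genes were detected in accumbens and 19238 and 18937 in dorsal striatum, for which a regional difference also stays open.

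With 4 libraries there are 3 splits into pairs, too few for a share under 0.05. The real split gave 186 genes past the threshold in edgeR and the highest of the others gave 0, so 1 split, the real one, reached this count. The 2 others had 182 and 159 genes at an unadjusted p under 0.05 (edgeR). Both mixed the regions within each group, so regional differences counted there as spread within groups. A low count was thus favoured in advance, and 186 against 0 cannot decide on the grouping.

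Ccdc153, a gene of ciliated ependymal cells, had 70 counts in dorsal striatum and 0 in accumbens, at least 17-fold higher against a floor of 3 counts per region (edgeR adjusted p = 0.0591). Dorsal striatum replicate 2 had 12 Oxt, 16 Gal, 55 Gabre and 25 Greb1 counts, and dorsal striatum replicate 1 had 1, 4, 5 and 7. Xist had 9, 10, 0 and 6 counts in the 4 libraries. Rn45s was higher in accumbens by a log2 fold change of 1.27 (edgeR adjusted p = 0.0348), and Lars2 by 1.22 (0.0458).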
